A study of Solanum tuberosum with 10 samples.

How the data were processed

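Gene expression was measured by RNA sequencing in explants of in vitro potato (Solanum tuberosum, cultivar Desirée). Per the labels' protocols, node segments bearing a leaf were cut from plantlets 4 weeks old. For the treated arm, 90 explants in 40 ml of liquid Murashige and Skoog medium in a 50 ml beaker were treated in an ultrasonicator. The sample records give the same explant number, volume and beaker for the control libraries. Whether control explants were also placed in liquid medium is not stated here. If they were not, immersion and ultrasound cannot be told apart in the comparisons of arms. Treated and untreated explants were then grown on hormone-free medium and sampled directly after treatment (0 h), after 24 h and 48 h, and after 1 and 4 weeks. RNA of 3 biological replicates was pooled before library preparation, so each treatment and time has 1 library and the data hold 10 libraries.

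Per the labels' protocols, libraries were made with a stranded mRNA kit, and the series description also speaks of rRNA removal and of 150 bp paired reads at an expected 100 M reads per sample. Per the submitters' processing notes, the tools were Trim Galore 0.5.0, FastQC 0.11.5 and HISAT2 2.1.0. The genome build, the annotation release, the counting program, its strand setting and its treatment of multiply mapped reads are not given in the sources used here. The deposited table holds raw counts per feature, which are whole numbers with no sign of normalization, and every column of values in it was matched to a sample by its label. Read counts of gene families with near-identical copies, of overlapping genes and of antisense genes are therefore uncertain, and 1246 of the compared features overlapped the one before them on the chromosome. PCR duplicates cannot be told from independent molecules, so intervals and floors cover counting error only.

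The table lists 40430 features, of which 39021 are gene models and 1409 are noncoding features. No count in any library was recorded for 11264 of them. None of the feature identifiers was found in the reference gene table used here (0 matched), and 0 features carried a description. The table itself pairs 22 gene models with a symbol and 1240 noncoding features with a class name. Coordinates are given as the table gives them, on a build that is not named. The 29 gene lists written before the data were examined were matched against symbols and descriptions and found a member in 0 cases, so no list was tested and no theme is named.

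Counts were analysed with edgeR 4.0.16 in R 4.3.3. Features were kept by filterByExpr on treatment, which left 24421, and libraries were scaled by TMM. The quasi-likelihood F-test was used with Benjamini-Hochberg adjustment at 0.05. The ultrasound effect was tested with time as a block, so the replication comes from the 5 times at which both arms were sampled and the test concerns a change common to those times. Time effects were tested in the same additive model, which has 4 residual degrees of freedom, with 2 libraries per time. Whether the ultrasound effect differed between the early times (0 h, 24 h and 48 h) and the late times (1 week and 4 weeks) was tested with an interaction term. P-values measure the spread between pooled libraries and not between plants. Each treatment and time has 1 library, so in the additive model this spread is the departure of the time pairs from a common ultrasound effect. An ultrasound effect specific to 1 time enters it and lowers the power of these tests. In the time tests the 2 arms stand in for replicates. Standard errors of log2 fold changes are approximate, being the size of the log2 fold change divided by the root of the F statistic.

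At each single time there is 1 library per arm and no test. The ratio of TMM-scaled counts is given with an exact 95% binomial (Clopper-Pearson) interval, and a feature counts as apart when its whole interval lies beyond 2-fold. Expression is given as CPM, counts scaled to library size with the TMM factor, and a pseudocount of 0.5 CPM was added before log2 transformation. A ratio against a library with no count was computed against a floor of 3 counts in that library and is a lower bound for that floor, while the exact interval printed beside it covers the error of both counts and begins lower. Total counts per library ran from 122786170 to 161153911, so that, with the TMM factor, 3 counts correspond to 0.0165 to 0.0312 CPM.

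The rule for named genes, set before the data were examined, asked for genes with a functional description, and for identifiers only (at most 2 higher and 2 lower per comparison) where none could be paired. For each time against 0 h it took the 5 largest rises and the 5 largest falls among called genes at a mean of at least 5 CPM that moved the same way in both arms. At each single time it took the 6 furthest above and below 1 by the interval bound nearest 1, and for early against late the 5 smallest p per direction. Of these, the text prints a part. The 22 genes with a symbol were taken as those with a description, a choice made once the table had been seen. Of these, 20 passed the filter. For ultrasound over all times the rule took the 12 largest changes per direction, or failing 5 calls the 8 smallest p, at a mean of at least 1 CPM and with the same direction in all 5 pairs, which 0 of the 20 met. CHS1B and NDA1 are printed for that comparison outside the rule and were chosen after their values were seen.

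The model was tested on simulated counts for the same 24421 features. For ultrasound over all times it recovered 11.9% of genes changed 2-fold, 71.6% of those changed 4-fold and 81.8% of those changed 8-fold, with 9 false calls. For 24 h against 0 h it recovered 0 of 67 at 2-fold, 19.4% at 4-fold and 50% at 8-fold, with 2 false calls. For early against late it recovered 0 of 67 at 2-fold, 2.99% at 4-fold and 40.9% at 8-fold, with 5 false calls. The simulation of 24 h against 0 h held no other time effect and changed only 66 or 67 features per fold. In the data 4859 features were called for that contrast, so the adjusted threshold was stricter in the simulation. Its recovery is therefore not the power of the time test in the data. In both ultrasound simulations the changed features that were called eased the adjusted threshold for the rest. The data gave 0 calls for either ultrasound result, so a lone changed gene met a stricter threshold. Those shares are therefore not the power to find a few changed genes in the data.

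Alternatives were DESeq2 (1.42.0), limma-voom (limma 3.58.1), median-ratio size factors, total counts without a composition factor, no filter, a stricter filter (at least 5 CPM in at least 5 libraries), leaving out each time's pair of libraries, and no time block. A further alternative divided early from late times by the tissue label, with 48 h, 1 week and 4 weeks as late. For the single times the alternatives were other scalings, an interval beyond 4-fold, and a point estimate beyond 2-fold with at least 50 counts in 1 library. Alternatives added after seeing the data left out rRNA features, the control library at 24 h or the ultrasonicated library at 0 h, and compared the times after 0 h with one another. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for ratios, resampling and plots. Beyond the 16 splits of the libraries that part every time pair, 14 other splits were drawn, 30 in all, to keep the repeated fits short.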

Results

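Expression profiles of potato explants were compared between an ultrasonicated and a control arm directly after treatment (0 h), after 24 h and 48 h, and after 1 and 4 weeks, with 1 library (a pool of 3 biological replicates) per arm and time. Total counts ran from 122786170 in the control library at 24 h to 161153911 in the control library at 48 h. Between 23981 (ultrasonicated, 0 h) and 27356 (control, 48 h) features had at least 1 count. The TMM factor was lowest, 0.688, in the ultrasonicated library at 0 h and 0.885 in its control, and lay between 0.975 and 1.136 in the other libraries. rRNA features took 2.19% of counts in the control library at 24 h (95% exact interval 2.19 to 2.19) and from 0.0333% to 0.423% in the other 9 libraries.

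Time separated the libraries more than treatment did. Each library correlated best, across features, with the library of the other arm at its own time, from r = 0.94 at 0 h to r = 0.979 at 48 h. Features are not independent replicates, so these correlations describe the libraries. The SD of log2 ratios between arms was 0.931 at 0 h, 0.656 at 24 h, 0.513 at 48 h, 0.722 at 1 week and 0.583 at 4 weeks. Between consecutive times within an arm it ran from 0.759 (control, 24 h to 48 h) to 1.4 (ultrasonicated, 0 h to 24 h). Several of these steps lay below the 0.931 between the arms at 0 h.

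**Figure D1:**
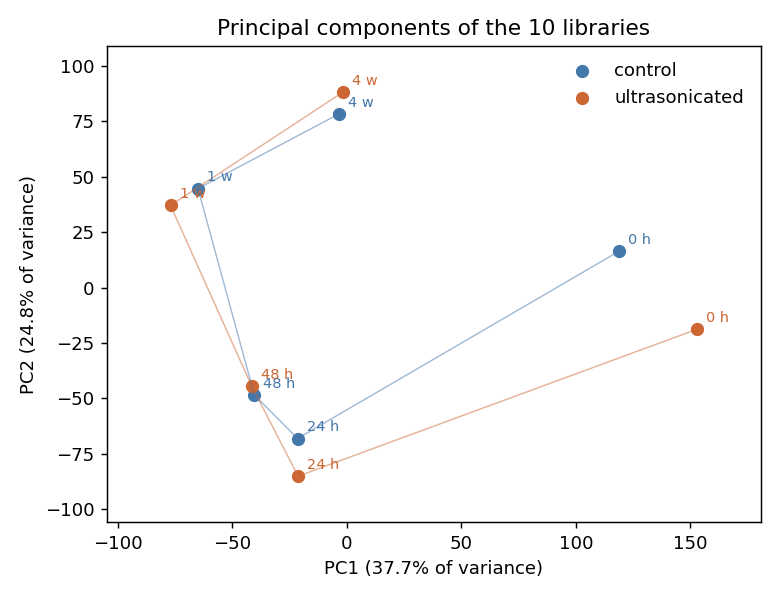
Scores of the 10 libraries on the first and second principal components of log2 CPM (37.7% and 24.8% of variance), with lines joining the times of each arm. The 0 h libraries lie apart at PC1 scores of 119.0 (control) and 153.0 (ultrasonicated), and the arms of each later time lie close together.

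The first question was which genes changed with time after cutting, over both arms. The tissue label sets 48 h, 1 week and 4 weeks apart from 0 h and 24 h. Changes from 0 h to those later times can therefore not be told apart from a difference in the tissue sampled. METK1, an S-adenosylmethionine synthase (PGSC0003DMG400018292, chromosome 1, 78724855 to 78727233), went from 1460 CPM (control) and 891 CPM (ultrasonicated) at 0 h to 188 and 210 CPM at 24 h. Its log2 fold change was -2.55 (SE 0.301, edgeR Benjamini-Hochberg adjusted p = 0.0027), lower in both arms. SN2, a snakin-type antimicrobial peptide (PGSC0003DMG400001598, chromosome 1, 87145671 to 87146801), also fell (log2 -2.42, SE 0.488, edgeR adjusted p = 0.0139). So did RBCS-2C, a small subunit of Rubisco (PGSC0003DMG400012666, chromosome 2, 41192215 to 41193945; log2 -2.21, SE 0.612, edgeR adjusted p = 0.0406), and EIF5A5, a translation factor (PGSC0003DMG400024558, chromosome 3, 55475040 to 55477312; log2 -1.81, SE 0.298, adjusted p = 0.00689). CHS1B, a chalcone synthase of flavonoid synthesis (PGSC0003DMG400029620, chromosome 9, 58356999 to 58359082), rose by 4.4 (SE 0.509, edgeR adjusted p = 0.0026), from 0.813 and 1.91 CPM to 23.8 and 30.1 CPM.

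WAXY, a granule-bound starch synthase (PGSC0003DMG400012111, chromosome 8, 56782186 to 56785790), rose by 2.56 at 24 h (SE 0.611, edgeR adjusted p = 0.0251). IVD, an isovaleryl-CoA dehydrogenase of branched-chain amino acid breakdown (PGSC0003DMG400008113, chromosome 11, 41104262 to 41111799), rose by 1.7 (SE 0.314, edgeR adjusted p = 0.0104). WHY1, a Whirly-type DNA-binding protein (PGSC0003DMG400017627, chromosome 5, 5903924 to 5907317), rose by 1.57 (SE 0.304, adjusted p = 0.0122) and EIF5A4 (PGSC0003DMG400026829, chromosome 1, 51719395 to 51722322) by 1.07 (SE 0.314, edgeR adjusted p = 0.0492). All 9 of these genes moved the same way in both arms. Of the 20 genes with a symbol that were tested, 5 rose, 4 fell and 11 did not pass, and 11 passed when adjusted over the list alone, a list recognised only once the table had been seen.

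Over all features, 4859 of 24421 changed at 24 h by edgeR, 2311 of them higher and 2548 lower. With total counts as the scaling the split was 3749 higher and 1818 lower, the median feature shifting from 0.01 to 0.35, and the call of RBCS-2C ended (log2 -1.91, edgeR adjusted p = 0.0648). With rRNA features left out 4928 features were called. Without the control library at 24 h 1326 were called, 555 higher and 771 lower, and the calls of SN2 (log2 -2.39, edgeR adjusted p = 0.0987), RBCS-2C (-1.55, 0.237), EIF5A5 (-1.64, 0.0643), WHY1 (1.4, 0.0875), WAXY (2.36, 0.115) and EIF5A4 (0.62, 0.276) ended. Without the ultrasonicated library at 0 h 3095 features were called, 1239 higher and 1856 lower, and the calls of WHY1 (1.31, edgeR adjusted p = 0.0569), IVD (1.66, 0.051) and EIF5A4 (1.07, 0.128) ended. The falls of SN2 (log2 -3.1) and RBCS-2C (log2 -3.02) were larger there, over 1.5 times as unlogged fold changes. Without the pair at 48 h 3330 features were called, 1439 higher and 1891 lower. The call of RBCS-2C also ended without the pair at 48 h (-2.2, edgeR adjusted p = 0.075) or at 4 weeks (-2.28, 0.0517), and that of EIF5A4 without the pair at 48 h (0.0808), 1 week (0.0628) or 4 weeks (0.065). It further ended with median-ratio size factors (edgeR adjusted p = 0.0571), without a filter (0.0513) and with the stricter filter (0.0532).

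At 48 h, in a comparison that shares its 0 h libraries with that at 24 h, CHS1B stood 4.71 log2 units above 0 h (SE 0.519, edgeR adjusted p = 0.00189), WAXY 2.71 (SE 0.624, adjusted p = 0.0215) and WHY1 1.88 (SE 0.307, adjusted p = 0.00611). Falls were called for METK1 (log2 -1.72, edgeR adjusted p = 0.0071), SN2 (-1.95, 0.0274), RBCS-2C (-2.38, 0.0301) and EIF5A5 (-1.89, 0.00552). Of the 20 genes, 3 rose, 4 fell and 13 did not pass, and 7 passed when adjusted over the list alone. In all, 5002 features changed, 2426 higher and 2576 lower, against 4633 higher and 1524 lower with total counts, where the median feature shifts from 0.04 to 0.53. Total counts also ended the calls of SN2 (-1.51, edgeR adjusted p = 0.0627) and RBCS-2C (-1.95, 0.0533). Without the ultrasonicated library at 0 h the falls of SN2 (log2 -2.64) and RBCS-2C (log2 -3.12) were larger, over 1.5 times as unlogged fold changes. The balance of directions turned with rRNA features left out (2542 higher, 2530 lower) and without the pair at 4 weeks (2345 and 2249).

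At 1 week SN2 was at its lowest of the 5 times in both arms, 56.1 CPM in control and 127 CPM in ultrasonicated explants, a log2 change of -3.7 from 0 h (SE 0.52, edgeR adjusted p = 0.00279), and of -4.48 without the ultrasonicated library at 0 h. RBCS-2C stood at 962 CPM in control and 1660 CPM in ultrasonicated explants, against 2060 and 688 CPM at 0 h. The arms thus moved in opposite directions, and the log2 difference of 0.01 from 0 h, which did not pass the test, averages them. CHS1B (4.51, adjusted p = 0.00125) and WHY1 (2.24, adjusted p = 0.00265) stood above 0 h, as did NDB1, an alternative NAD(P)H dehydrogenase of mitochondria (PGSC0003DMG400021670, chromosome 10, 4157577 to 4163576; 0.91, adjusted p = 0.0488). EIF5A5 fell by 1.24 (edgeR adjusted p = 0.0201). Of the 20 genes, 3 rose, 2 fell and 15 did not pass, and 5 passed when adjusted over the list alone. The call of NDB1 ended without the ultrasonicated library at 0 h, where its log2 change was 0.49 (adjusted p = 0.276), and that of EIF5A5 ended there too (edgeR adjusted p = 0.0539) and with total counts (0.0652). That of NDB1 also ended without the pair at 24 h (edgeR adjusted p = 0.0648), 48 h (0.0728) or 4 weeks (0.0651), with median-ratio size factors (0.0566), without a filter (0.054) and with the stricter filter (0.0544). In all, 6024 features changed, 3055 higher and 2969 lower, against 5084 higher and 2138 lower with total counts, where the median feature shifts from 0.06 to 0.46. The balance turned without the ultrasonicated library at 0 h (1623 higher, 2439 lower), with median-ratio size factors (2863 and 3091), with the stricter filter (2301 and 2738), with DESeq2 (4159 and 4199) and without the pair at 48 h (2277 and 2333).

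By 4 weeks CHS1B alone among the 20 genes passed the test, at 2.9 log2 units above 0 h (SE 0.477, edgeR adjusted p = 0.00821), and it was also the 1 gene that passed when adjusted over the list alone. METK1 stood at 1760 and 1920 CPM, and EIF5A5 at 1160 and 832 CPM, neither of them past the test. In all, 2858 features changed, 869 higher and 1989 lower, against 2758 higher and 1456 lower with total counts, which turns the balance of directions and shifts the median feature from 0.1 to 0.61. The count was 1854 without the ultrasonicated library at 0 h (374 higher, 1480 lower) and 1977 without the pair at 48 h (444 and 1533). Over the 5 times together, 6835 features (28%) changed by the F-test, and 4382 did without the control library at 24 h.

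**Figure D2:**
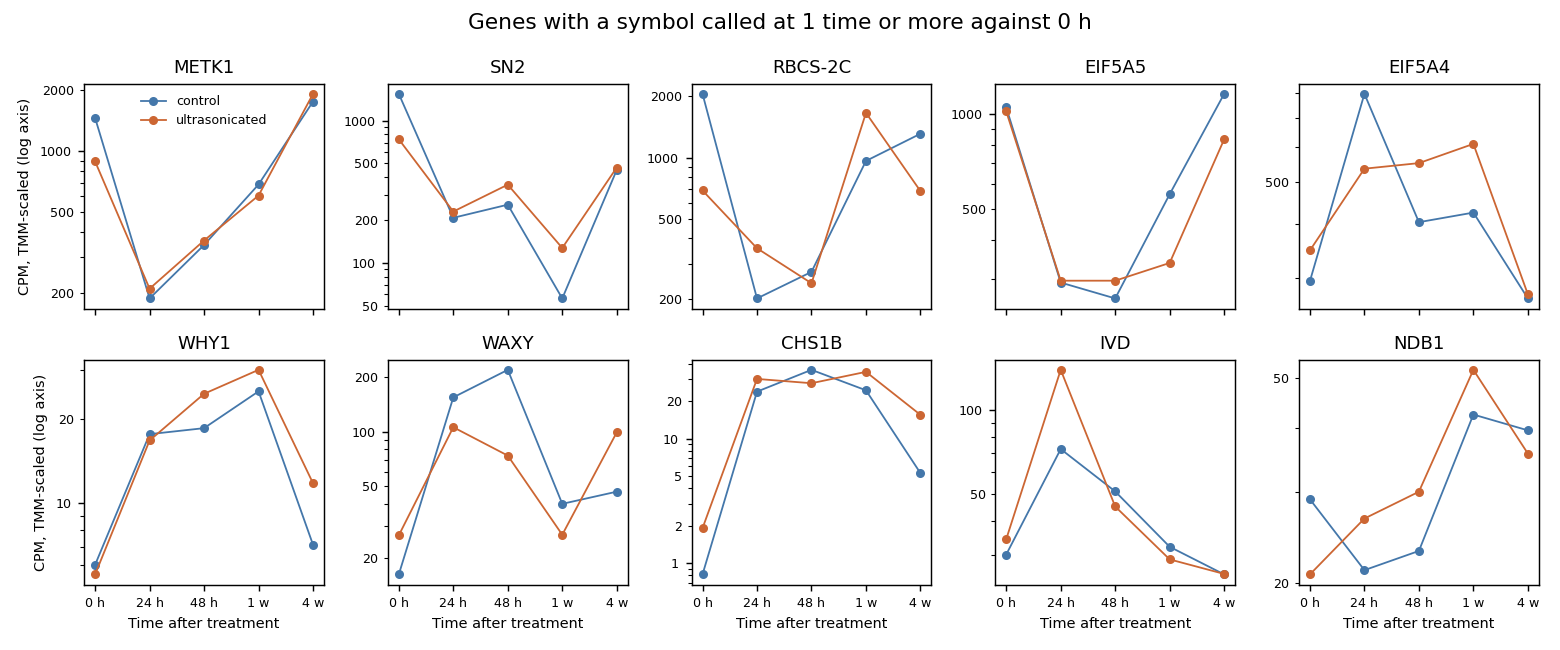
CPM on a log axis at each time for the 10 genes with a symbol that were called at 1 time or more against 0 h, with 1 point per library and no error bars. METK1, for example, went from 1460 to 188 CPM between 0 h and 24 h in control explants and stood at 1760 CPM at 4 weeks.

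Among genes without a symbol, PGSC0003DMG400025797 (chromosome 1, 84659395 to 84660407) had 85.69 and 114.61 CPM at 0 h and 0.01 and 0.04 CPM at 24 h, a log2 change of -11.99 (SE 1.07, edgeR adjusted p = 0.00194). Its 24 h values lay near the floor of 3 counts (0.0251 CPM in control and 0.0229 CPM in ultrasonicated explants), so the size of this fall is poorly fixed. This gene was among the largest falls at 24 h, 48 h and 1 week. PGSC0003DMG400020703 (chromosome 7, 7686336 to 7686831) had no count at 0 h in either arm, 9.12 and 8.47 CPM at 24 h and 42.51 and 33.63 CPM at 48 h (adjusted p = 0.0281 at 48 h).

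The second question was which genes ultrasound changed in common over the 5 times. For no gene with a symbol was the direction the same in all 5 pairs. Of 24421 features 0 passed edgeR's adjusted threshold, 815 (3.34%) had an unadjusted p under 0.05, and the smallest adjusted p was 0.622. Without any effect a share of about 0.05 would be expected under that p, so the 815 are no sign of one. DESeq2 called 53, 8 higher and 45 lower, of which 49 had the same direction in all 5 pairs and 10 had over 0.5 of their summed CPM in 1 library. limma-voom called 0. Among the 20 genes with a symbol CHS1B had the smallest p. It stood 0.64 log2 units above control (SE 0.287) and was higher in 4 of 5 pairs, with an edgeR adjusted p = 0.999. The 20 genes lay between -0.41 (NDA1) and 0.64. Among the genes without a symbol, those with the smallest p and the same direction in all 5 pairs included PGSC0003DMG400027888 (chromosome 7, 38959941 to 38964852; log2 difference 1.83, SE 0.243, adjusted p = 0.622) and PGSC0003DMG400011815 (chromosome 6, 40610373 to 40612477; -1.66, SE 0.195, adjusted p = 0.622), given as values and not as changes. All 5 pairs had the same direction in 6.3% of features, and independent directions would give 6.25%.

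Whether the ultrasound effect differed between early and late times was tested next. No feature passed with edgeR (0 of 24421) or limma-voom (0), while DESeq2 called 199. At an unadjusted p under 0.05 edgeR had 1021 features (4.18%), again below a share of 0.05. The smallest p among the genes with a symbol was that of NDA1, another alternative NAD(P)H dehydrogenase (PGSC0003DMG400004168, chromosome 6, 3238431 to 3242949). Its ultrasound effect was 1.69 log2 units higher at the late times (SE 0.416, edgeR adjusted p = 1, and 0.0986 adjusted over the list alone), and DESeq2 gave it an adjusted p of 0.0382. In the other direction EIF5A5 had the smallest p, at -0.66 (SE 0.315, edgeR adjusted p = 1). Among genes without a symbol PGSC0003DMG400021895 (chromosome 5, 15059048 to 15061686) had -2.82 (SE 0.318, edgeR adjusted p = 0.602).

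The arms were then set side by side at each time, where each value comes from 1 library per arm and has no replicate check. At 0 h the ultrasonicated library had 0.333 times the control level of RBCS-2C (interval 0.331 to 0.336), 0.417 times that of NDA1 (0.381 to 0.456) and 0.478 times that of SN2 (0.473 to 0.482). HMG3, a hydroxymethylglutaryl-CoA reductase of isoprenoid synthesis (PGSC0003DMG400018679), had a ratio of 1.98 (1.86 to 2.1) and CHS1B 2.35 (1.82 to 3.05), neither wholly beyond 2-fold. PCM6, a calmodulin (PGSC0003DMG400022693), had a log2 ratio of 0.28 and EIF5A2 (PGSC0003DMG400007830) 0.25, and both turned to -0.09 and -0.12 with total counts, a scaling under which the median feature at 0 h shifts by -0.355. Of 24421 features 2834 were higher and 2733 lower beyond 2-fold (1941 and 4454 with total counts). The feature without a symbol furthest above control by its interval was PGSC0003DMG400024476 (chromosome 3, 53778612 to 53779610), with 0.0972 CPM in control and 704 CPM in ultrasonicated explants, followed by PGSC0003DMG400009255 (chromosome 11, 13518704 to 13519520), with 5.08 and 3690 CPM. Of features lower than control, PGSC0003DMG400007096 (chromosome 7, 52462910 to 52465080) had 401 control counts and 0 in the ultrasonicated library, at least 114-fold lower against the floor of 3 counts (interval from 92.1-fold). Features higher beyond 10-fold (411) held 12.6% of the ultrasonicated library's counts and 0.357% of the control library's.

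At 24 h IVD had a ratio of 1.93 (1.88 to 1.98) and RBCS-2C 1.77 (1.74 to 1.8). ATPE (PGSC0003DMG400025106) and RPOA (PGSC0003DMG400014075), labelled with the names of plastid genes and counted on chromosomes 5 and 12, had 22 against 142 and 87 against 270 counts in the ultrasonicated and control libraries, ratios of 0.142 (0.0862 to 0.223) and 0.295 (0.229 to 0.377). EIF5A4 stood at 0.674 (0.667 to 0.681). Among features without a symbol, PGSC0003DMG400001372 (chromosome 2, 45423918 to 45424907) had 1.1 CPM in control and 65.2 CPM in ultrasonicated explants. PGSC0003DMG400046976 (chromosome 1, 51059758 to 51060718) had 58.1 and 0.0229 CPM. In all, 1269 features were higher and 1747 lower, in a pair whose control library had 2.19% rRNA and whose ultrasonicated library had 0.066%.

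At 48 h WAXY had 0.335 times its control level (0.328 to 0.343), 73.9 against 220 CPM, and NDA1 0.421 times (0.384 to 0.461). UBI3, a ubiquitin fusion gene (PGSC0003DMG400005199), had a ratio of 1.52 (1.51 to 1.53). RPOA stood at 3.65 (2.67 to 5.07), on 159 against 54 counts. PGSC0003DMG400010147 (chromosome 3, 44440705 to 44441519) had 145 CPM in control and 6.36 CPM in ultrasonicated explants. This pair was the closest of the 5, with 644 features higher and 1232 lower.

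At 1 week SN2 had 2.26 times its control level (2.2 to 2.32), NDA1 1.9 times (1.79 to 2.01) and RBCS-2C 1.73 times (1.72 to 1.74), while EIF5A5 had 0.605 times (0.598 to 0.611) and HMG3 0.618 times (0.584 to 0.654). ATPE had 0 control counts and 59 counts in the ultrasonicated library. RPOA stood at 2.32 (1.74 to 3.13). PGSC0003DMG401030252 (chromosome 1, 615361 to 617661) had 5105 control counts and 1 count in the ultrasonicated library. Beyond 2-fold, 1645 features were higher and 2533 lower.

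At 4 weeks CHS1B had 2.94 times its control level (2.71 to 3.19), 15.5 against 5.28 CPM, and WAXY 2.12 times (2.07 to 2.18), 99.3 against 46.7 CPM. RPOA had 0.211 times (0.151 to 0.291) and RBCS-2C 0.521 times (0.517 to 0.524). PGSC0003DMG400014104 (chromosome 8, 1473270 to 1474875) had 0 control counts and 465 counts in the ultrasonicated library, at least 144-fold higher against the floor of 3 counts (interval from 117-fold). Beyond 2-fold, 1452 features were higher and 1559 lower (1576 and 1436 with total counts, which turns the balance).

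**Figure D3:**
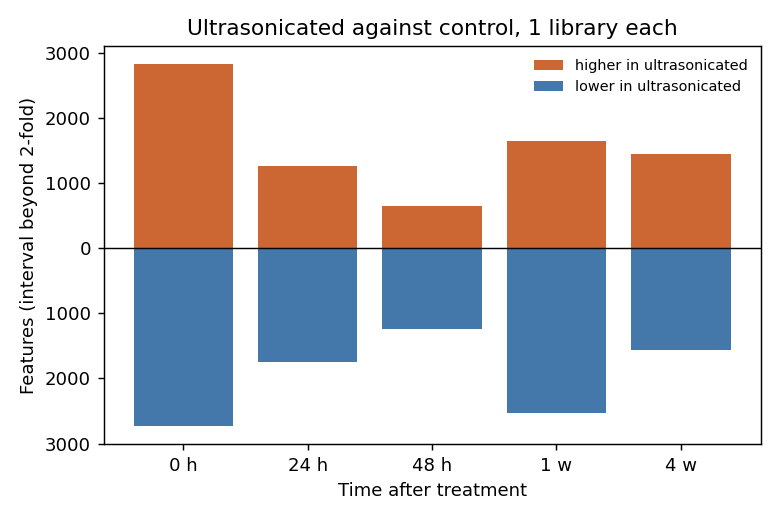
Number of features whose exact 95% interval of the ratio lay wholly beyond 2-fold, higher (above the zero line) or lower (below it) in the ultrasonicated library than in the control library of the same time. The 0 h pair has 5567 such features and the 48 h pair 1876, each from 1 library per arm.

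Log2 ratios at one time were weakly related to those at another. Across 24421 features, Pearson's r between times lay between -0.24 (48 h and 4 weeks) and 0.27 (48 h and 1 week) over the 10 pairs of times, with Spearman's rho of -0.27 and 0.3 for the same pairs. Of the 10661 features beyond 2-fold at 1 time or more, 689 were so in the same direction at 3 times or more, and 2785 were higher at 1 time and lower at another.

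**Figure D4:**
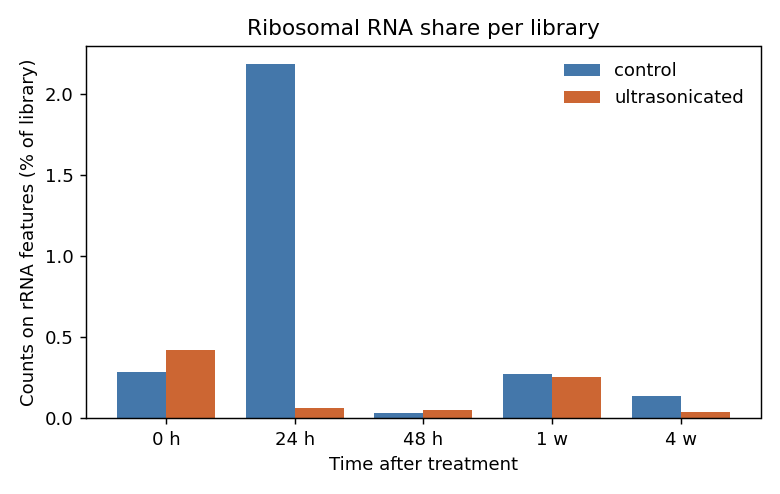
Share of each library's counts on rRNA features, in percent, by time and arm, from 1 library per bar. The control library at 24 h has 2.19% and the other 9 libraries have at most 0.423%.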

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

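Each result here is a gene with a symbol whose ratio lay wholly beyond 2-fold in opposite directions at different times. Each time has 1 library per arm, and the difference between times was not tested gene by gene at that resolution. The early against late test called 0 features with edgeR.

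SN2 had a log2 ratio of ultrasonicated to control of -1.07 at 0 h and 1.18 at 1 week. WAXY had -1.58 at 48 h and 1.09 at 4 weeks. RPOA had -1.76 at 24 h, 1.87 at 48 h and -2.24 at 4 weeks, on 47 to 270 counts per library at those times. In the same pairs, control first, the rRNA share was 2.19 and 0.066% at 24 h, 0.0333 and 0.051% at 48 h, and 0.136 and 0.0402% at 4 weeks. Features of the group II intron class had 10.4 and 4.72, 0.936 and 3.38, and 3.4 and 0.963 CPM. These moved in the direction of RPOA at those 3 times and against it at 0 h, where RPOA had a log2 ratio of -0.62, the rRNA share was 0.288 and 0.423%, and the intron class had 7.42 and 16.6 CPM. At 1 week RPOA had 1.22, the rRNA share 0.275 and 0.256%, and the intron class 2.98 and 4.31 CPM. Whether they share an origin was not tested. ATPE had -2.82 at 24 h and at least 4.31 at 1 week, the latter against a control library with 0 counts and computed against the floor of 3 counts (interval from 15.6-fold).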

How the results depend on the processing

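Leaving out single libraries or rRNA features was chosen after seeing the data. With DESeq2 the counts were 53 for ultrasound over all times, 199 for early against late, 11654 for the F-test over times, and 7357, 7522 and 5208 for 24 h, 48 h and 4 weeks against 0 h, and the cause was not tested. edgeR gave 0 for both ultrasound results under every other setting run, limma-voom gave 0, and so did every pair left out.

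Leaving out libraries gave 1326 (without the control library at 24 h) to 4402 for 24 h against 0 h, 1854 (without the ultrasonicated library at 0 h) to 2566 for 4 weeks, and 4382 to 6557 for the F-test. A lone library is then assumed to vary like the others. An interval beyond 4-fold left 2082, 894, 274, 1453 and 946 features at the 5 times in order, fewer by construction.

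Of the other 95 values of these counts all lay within 1.5 times. For named genes, 222 alternative test values kept their call, 29 lost it, and 0 called values reversed, while 63 ratios at single times kept their interval and 57 moved. EIF5A4 at 24 h and NDB1 at 1 week lay nearest the threshold. Over the alternatives the adjusted p (edgeR, DESeq2 or limma-voom, Benjamini-Hochberg) ran from 0.013 to 0.276 for EIF5A4 and from 0.0237 to 0.276 for NDB1. The planned tests of gene lists, and the control arm alone at 24 h, were not run. No paired analysis by replicate number was possible because each group has 1 library. Depth limits ATPE and RPOA, whose ratios rest on few counts.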

Other observations

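The tests of splits, of rRNA in the 10-fold set and its levels, of rRNA added to other features, of the spread at 0 h outside the 10-fold set, of exchanged libraries, of scaling and carried-over reads for the 0 h set, and the count over all such sets, were chosen only after the result was seen, as were the contrasts between later times.

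Comparisons between later times add to the time course, and those that start at 24 h also cross the tissue label. Between 24 h and 48 h edgeR called 0 features (3269 at an unadjusted p under 0.05; no other tool was run), between 48 h and 1 week 316, between 1 week and 4 weeks 869, and between 24 h and 4 weeks 3380. These counts depend on the other times in the model. The count between 1 week and 4 weeks was 1761 without the pair at 0 h, 104 without that at 24 h and 27 without that at 48 h. Between 48 h and 1 week it was 735 without the pair at 0 h and 162 without that at 24 h, and between 24 h and 4 weeks 1940 without that at 48 h. Among noncoding classes, features of the signal recognition particle RNA had 82.4 CPM in the control library at 24 h and from 2.07 to 14.3 CPM in the other 9 libraries. That library also had the highest rRNA share (2.19%). Other classes varied less, such as U6, with 2.58 to 6.1 CPM over all libraries.

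Some sets of features apart between the arms lay next to each other on the chromosomes more often than after shuffling. The features higher beyond 10-fold at 0 h formed 32 neighbouring pairs without overlap, against a mean of 6.4 and a highest value of 17 in 1000 shuffles. The longest run held 6 neighbours on chromosome 6, from 56893292 to 56908742. Features lower beyond 4-fold at 1 week formed 85 pairs (highest of the shuffles 49), while those higher at 1 week formed 23 (highest 24). Reads shared between tandem copies were not examined.

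A first pattern is the low level of some features in the ultrasonicated library at 24 h. Of 185 features lower beyond 10-fold, 36 are rRNA features, and the median correlation of the other 149 with summed rRNA over the other 8 libraries was 0.34 (two-sided exact permutation p = 0.0512 over 40320 orders; median Spearman 0.29; median r 0.47 without the 2 libraries farthest from the median). Minimums of 5, 10 and 20 CPM in the control library were the only ones looked at. The median was then 0.89, 0.93 and 0.94 over 63, 49 and 39 features. The first of these lay under the bound set for the test, so rRNA may account for part of the abundant members. With rRNA added as described next, the 49 features gave a median of 0.97 (0.95 to 0.98 over 100 draws). Of them 69.4% passed 0.8, against 86.9% (77.6 to 94.9) with rRNA added. The 100 features below 10 CPM set the value of the whole set. Their median was 0.09, against 0.5 (0.38 to 0.59) with rRNA added. The observed values thus lay below the simulated ranges, which rest on an assumed profile. For these 100 the level expected from rRNA also lies near or under the pseudocount, and the origin cannot be told apart. Of the 1704 features lower beyond 2-fold that are not rRNA features, 3.87% correlated above 0.8 (12% of the 391 at 10 CPM or more), and 1.63% of all features did, but with each member's excess at 24 h added in proportion to rRNA to a feature of like level outside the set only 8.76% (20.4% of the 391) passed 0.8, so the 50% predicted before could not be met, and since these shares rest on an assumed profile the lower ones observed exclude nothing. The origin of the 2-fold set stays open too, and so does a response to ultrasound, which was not tested.

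A second pattern is that the 0 h pair was furthest apart. Outside the 10-fold set the SD of log2 ratios was 0.795 (bootstrap interval over features 0.786 to 0.803) at 0 h and at most 0.717 (0.706 to 0.728) later. With 1 factor for all features this SD changes only through the pseudocount, which weighs on low features. Among the more abundant features (11980 at 0 h) the SD was 0.739 at 0 h and at most 0.672 later. This argues against a few induced genes taking reads as the whole cause. The ultrasonicated library correlated at most at 0.872 with a library of another time and at 0.94 with its control, which argues against an exchange with another time. The correlation across genes between gene span and log2 ratio was -0.04 (bootstrap interval over genes -0.058 to -0.031), far from the -0.3 predicted. This argues against a loss that follows gene span as the whole cause and leaves a small part open. Gene span includes introns and transcript length was not examined, so a loss of long transcripts was not tested directly and stays open. An early response to ultrasound, a difference between the pools and an exchange of the labels within the pair stay open, and no test here separates them.

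The last pattern is that the 410 features higher beyond 10-fold at 0 h, rRNA left out, had median log2 ratios of 0.16 at 24 h and 0.12 at 48 h (both at percentile 100 among 10000 random lists matched on expression), and 0 at 1 week and -0.03 at 4 weeks (percentiles 21.8 and 2.36). Library scaling as the cause is argued against at 48 h by that percentile, which does not single out a lasting effect: of the 36 medians of 9 sets beyond 10-fold at times other than their own, 23 lay outside 95% of the random lists, among them 11 of the 18 at an earlier time, and the set lower at 4 weeks had 0.25 at 24 h and 0.2 at 48 h (both at percentile 100), while the set lower at 0 h had 0 and -0.08 (percentiles 90 and 13.6). Reads carried over from the 0 h library could not be excluded: 3.9% of the set lay below the share of the 0 h level that the median excess needs, too few to decide. At 48 h 247 of the 410 were higher and 163 lower. With the set bound at 4-fold the medians were 0.07, 0.04, -0.13 and -0.03 at the 4 later times. Under median-ratio size factors the medians at 24 h and 48 h came out at 0.28 and 0.21. That scaling slightly lowered single log2 ratios at 24 h (PCM6 from 0.17 to 0.16, UBI3 from -0.39 to -0.4). The higher medians therefore do not come from the scaling itself, and no weight is placed on them. An effect of ultrasound that lasts to 48 h stays open and untested.

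A hypothesis that ultrasound uniformly advanced or delayed the passage through the time course was tested by correlating the log2 ratio at 24 h, 48 h and 1 week with the change from the time before to the time after, within each arm. The 6 correlations across 20181 genes, control arm first, were 0.03 and 0.06 at 24 h, 0.1 and 0.17 at 48 h, and 0.03 and -0.07 at 1 week (Spearman's rho -0.16 to 0.12). They were low and had both signs, though only -0.07 was negative, and gave no clear sign of a uniform shift. The test was not calibrated on a shift of known size, so it cannot exclude one.

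For ultrasound over all times, all 16 splits of the libraries that part every time pair gave as many genes as the real one (0), and the highest of the others was 0. With 0 calls in the real split any split gives as many, so this outcome was fixed in advance and decides nothing. These 16 splits are also too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 815, 8 of the 16 gave as many or more, and the highest other gave 2061. The 14 other splits, which do not part every pair, gave at most 0 calls and 1842 at an unadjusted p. For early against late, all 10 choices of the late times gave as many features (0), and the highest of the others was 0. With 0 calls for the real choice this outcome was fixed in advance too, and 10 choices are too few for a share under 0.05.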
